A study of Mus musculus with 8 samples.

How the data were processed

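Liver RNA of 8 adult male C57BL/6 mice, 4 flox-only controls and 4 with both Zfp36l1 and Zfp36l2 deleted in the liver (dKO), was sequenced from total RNA. The labels number the mice 1 to 4 within each group, so each library is a separate animal. Per the submitters' processing notes, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 were used with genome build mm10, with no role or order given. The annotation, the strand setting and the filters of the counting are not given in the sources used here. Antisense and overlapping genes, and near-identical copies such as the Mup genes, can therefore share reads.

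The deposited table is named for FPKM, but its values are a signal of another kind. Within each library every value is a whole multiple of 1 step (100% of values within 0.001 of a whole number), the step differs between libraries, and no division by gene length is seen. The values are therefore gene read counts that the authors divided by 1 size factor per library, and they are called normalised read counts here. The design had assumed FPKM, and its test on a log scale was kept because the values are not raw counts. For dKO 1 the step lies so near 1 that an automatic check of whole steps cannot part it from rounding, although its values divide to whole reads like the others. Dividing by the steps gave back reads, in total 17384277, 17745944, 16839519 and 15253827 for controls 1 to 4 and 17273389, 17927767, 19299556 and 18413987 for dKO 1 to 4. A gene listed at 0 is below a floor of 3 counts per library, or 2.55 to 3.43 normalised read counts, and such floors and intervals cover counting error only. Mitochondrially encoded genes took 4.06% to 4.74% of the values in controls and 3.09% to 3.70% in dKO livers. Pairs of libraries within a group differed far beyond counting noise (chi-square per gene 15.0 to 32.5), so none was deposited as a copy of another.

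Of 22052 genes, 21796 identifiers matched a symbol. Values were taken as log2(value + 0.5) for the 20055 genes with a mean of 0.5 or more over all 8 livers, and group differences were tested with limma 3.58.1 (eBayes with a trend, R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held the group alone. For the targeted genes an exact permutation test was run beside it. Principal components used genes with a mean of 10 or more. The groups, tests, 40 gene lists, rule for named genes and alternatives were chosen before the data were examined, except the additions named below. The lists cover ZFP36-family targets, liver metabolism, sex-biased and zonal genes, inflammation, fibrosis, proliferation, stress, signalling and markers of other cells and tissues a whole liver can hold. They were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, for the 39 lists with 5 or more tested members. With an estimated correlation, camera's calls held for neutrophil markers, oncofetal genes, male-biased genes and bile acid synthesis. Fry asks whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. Its adjusted p was under 0.05 for all lists that camera called at the preset correlation except cholesterol synthesis (0.137). Of the lists that camera did not call, it was under 0.05 only for stellate cell markers (0.032), acute phase (0.0285), integrated stress (0.0263) and lipid droplet genes (0.0162). Counts of list members are given over all genes tested and adjusted over the list alone. Bulk values of cell type markers do not say which cells hold the RNA.

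The rule for named genes takes Zfp36l1, Zfp36l2 and Zfp36, the 12 genes with the largest rise and the 12 with the largest fall among those called, with a mean of 1 or more, no overlap between groups, a protein-coding biotype and an assigned name (no Gm or Rik symbols), up to 4 called members of each list with the smallest adjusted p, or up to 2 members with the highest mean for a list with none called, and 27 genes of liver metabolism, fibrosis, inflammation and growth fixed by name. Stability and single-liver deviations were computed for the genes the rule gives and 3 genes added after their values were seen, 188 in all; a few further genes are not reported here. The text describes part of them, and that part was shortened for length after the values had been seen. The 3' UTRs were taken from protein-coding transcripts of GENCODE release M21 on GRCm38, the assembly that mm10 names. They held a 3' UTR for 15517 tested genes and 99.8% of tested protein-coding genes. Genes with and without TATTTAT in the union of their 3' UTRs were compared with Fisher's exact test and a logistic model with log 3' UTR length and mean expression.

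On simulated values for these libraries, in which 200 of 19352 tested genes were changed, limma found 81% of genes changed 2-fold and 99% of those changed 4-fold, and 8.63% of its calls were genes that had not been changed. The changed genes lay well above the filter and rose or fell at random, and the size factors were known. In the data 38.2% of the tested genes were called, and more rose than fell by 2-fold or more. The simulated rates may therefore not carry over. Alternatives covered the pseudocount, the filter, 3 other scalings, sample weights, robust variances, the mouse number as a block, leaving out each liver in turn, the correlation in camera and the definition of the motif. The tests of A/T content and of the Mup sum replaced earlier ones that had left their questions undecided. Since the values carry no gene length, the planned rescaling to TPM was run as equal totals per library. Added after the values were seen were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, a filter at a mean of 10 and the deadenylation list without the deleted genes. edgeR called 7275 genes of 14210 and DESeq2 7520, against 7654 with limma. Figures were drawn with matplotlib 3.10.9.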

Results

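RNA was sequenced from the livers of 8 adult male C57BL/6 mice aged 8 weeks, each given corn oil into the peritoneum. Of these, 4 mice carried floxed Zfp36l1 and Zfp36l2 alleles without a recombinase (controls). The other 4 carried the same alleles with a Cre recombinase under the albumin promoter, which is active in hepatocytes (double knockout, dKO). ZFP36L1 and ZFP36L2 are RNA-binding proteins that bind AU-rich elements in the 3' untranslated region (UTR) of mRNAs and promote their decay. The libraries held 15253827 to 19299556 reads assigned to genes, over 22052 genes. Levels below are normalised read counts, given as mean ± SD over 4 livers per group, and changes are dKO against control on the log2(value + 0.5) scale with their standard error, which understates the change of genes with few reads. Unless stated otherwise, a named gene that rose or fell had all 4 dKO values on one side of all 4 control values.

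The design asks first whether the targeted transcripts were lower in the livers labelled dKO. Zfp36l1 (chromosome 12, 80107754 to 80113013, minus strand, mm10) fell from 1370.2 ± 194 to 226 ± 27.6, to 16.5% of the control mean (log2 change -2.60, SE 0.11, limma adjusted p = 1.7e-08). The single livers held 1320.5, 1336, 1182 and 1642 in controls 1 to 4 and 214, 213, 209.5 and 267 in dKO 1 to 4. Zfp36l2 (chromosome 17, 84183931 to 84187947, minus strand) fell from 1584 ± 393 to 796 ± 94.4, to 50.3% of the control mean (log2 change -0.96, SE 0.17, limma adjusted p = 0.000689). Its values were 1722, 1795, 997 and 1820 in the controls and 696, 794, 771 and 923 in the dKO livers. The third member of the family expressed in liver, Zfp36, stood at 2837 ± 448 in controls and 2371 ± 352 in dKO livers (log2 change -0.26, SE 0.12, limma adjusted p = 0.123). A 2-sided exact permutation test over the 70 assignments of the 8 livers gave p = 0.0286 for Zfp36l1 and for Zfp36l2, the smallest value it allows, and p = 0.2 for Zfp36. For Zfp36, limma's adjusted p ranged from 0.0421 without control 3 to 0.398 with quantile normalization, and was 0.047 without dKO 2. The counts cover whole genes, and which exons the floxed alleles remove is not given in the sources used here. Whole liver also holds cells other than hepatocytes, so the reads left do not tell how complete the deletion in hepatocytes was.

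**Figure D1:**
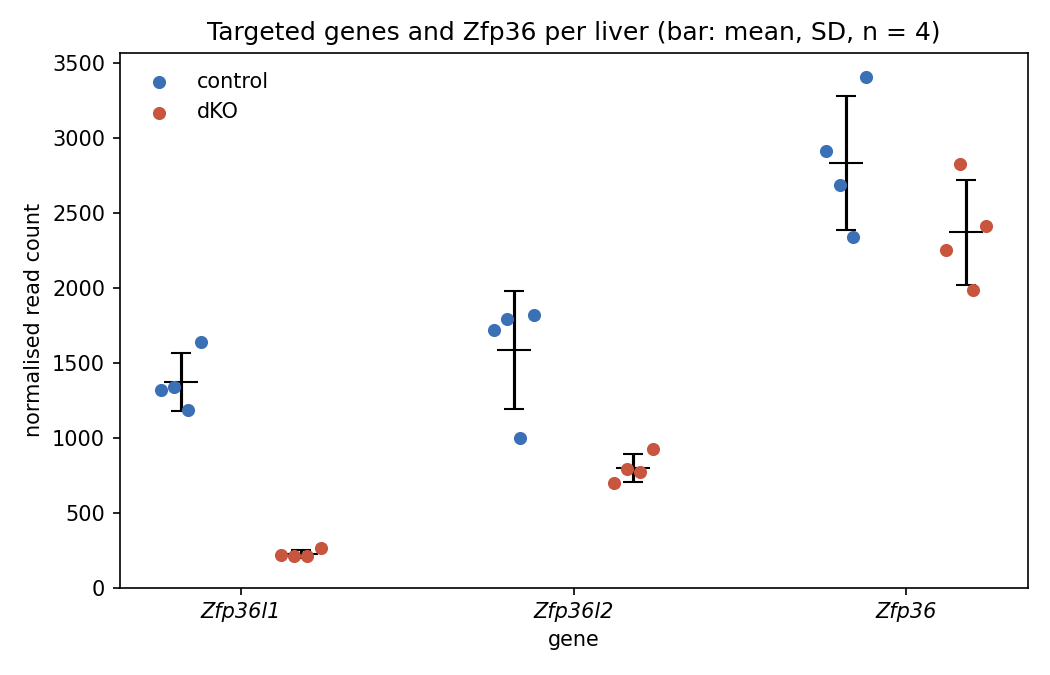
Normalised read count of Zfp36l1, Zfp36l2 and Zfp36 (vertical axis) in each liver, with controls in blue and dKO in red; black bars give the group mean and SD (n = 4). All 4 dKO livers lie below all 4 controls for Zfp36l1 (highest dKO value 267, lowest control 1182) and Zfp36l2 (923 and 997), and the groups overlap for Zfp36.

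The central comparison was dKO against control over all genes. Among 20055 genes tested with limma, 4244 were higher and 3410 lower in dKO livers (Benjamini-Hochberg adjusted p under 0.05), and 2559 were higher and 796 lower by 2-fold or more. With quantile normalization 3638 were higher and 4312 lower, which turned the balance, while 1901 were higher and 1339 lower by 2-fold or more. The highest rises included Lrtm2, from 1.05 ± 1.49 to 801 ± 43.5 (log2 change 9.52, SE 0.54), and Igdcc4, from 4.39 ± 3.97 to 937 ± 267 (log2 change 7.83, SE 0.41). Gldn had 1 read in the controls together and 1840 in the dKO livers, a ratio of 1606 with a 95% counting interval of 287.8 to 63460. Cacna1b and Sult2a2 had 0 reads in all controls, and their dKO means were at least 35.2-fold and 71.0-fold higher, against a floor of 3 counts per library. Sult2a2 varied between dKO livers, with values of 263, 116, 3.41 and 521 in dKO 1 to 4, the third from 4 reads, and its bound was 40.1-fold without dKO 4. Shc2, Rasal1, Tmc5, Dnah1 and Sprr1a rose by 7.33, 7.20, 6.97, 6.94 and 7.96 on the log2 scale, the last by 8.73 without control 4. Mup12, Mup17 and Hsd3b5 were among the genes with the largest falls and are described with the sex-biased genes. Protein-coding genes made up 4007 of the genes that rose and 3034 of those that fell. The groups did not overlap for 36.3% of the tested genes, against 2.86% by chance. The first principal component held 74.5% of the variance and parted the groups, and control 4 (score -43.3) lay nearer to the dKO livers (57.5 to 68.9) than controls 1 to 3 (-76.5 to -67.7). Camera tests of the fixed gene lists (preset correlation 0.01) called 17 lists higher and 9 lower, or 2 and 2 with an estimated correlation. The lists below are described by the counts of their members.

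**Figure D2:**
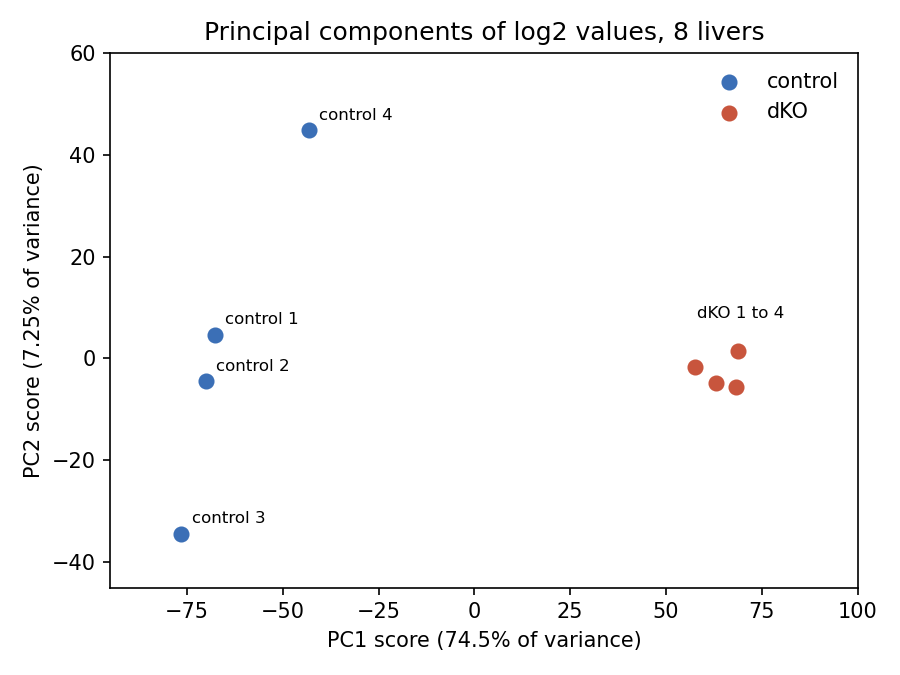
Scores of the 8 livers on the first (horizontal, 74.5% of variance) and second (vertical, 7.25%) principal components of log2 values; each point is 1 liver, controls in blue and dKO in red. The dKO livers lie between 57.5 and 68.9 on the first component and the controls between -76.5 and -43.3, with controls 3 and 4 apart from the others on the second.

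Because the deleted proteins act on AU-rich mRNAs, a list of mRNAs described as targets of the family was examined next. Of 45 tested members, 34 rose, 2 fell and 9 did neither (35 and 3 adjusted over the list alone), with a median log2 change of 1.57. Ccnd1, which encodes the cell cycle regulator cyclin D1, rose from 344 ± 139 to 2081 ± 318 (log2 change 2.66, SE 0.22, limma adjusted p = 1.7e-06). Klf6, a zinc finger transcription factor, rose from 219.9 ± 53.3 to 902 ± 150 (log2 change 2.05). The early response gene Ier3 (log2 change 2.88), the transcription factor Myc (1.63) and the cell cycle inhibitor Cdkn1a (1.17) also rose. Tnf, a cytokine and the classical target of the family, rose from 6.72 ± 10.1 to 28.2 ± 4.62 (log2 change 2.94, SE 0.73), and by 3.80 without control 4. For Tnf and the rest of the list, whole-liver levels do not part slower mRNA decay from a changed mix of cells. Vegfa fell by 0.37 on the log2 scale, with an adjusted p of 0.001 to 0.0748 over the alternatives, the highest with quantile normalization, which ends the call. Notch1 stood at 529.5 ± 115 and 453 ± 31.1 (limma adjusted p = 0.27). The list's camera adjusted p = 2.1e-08, and adjusted p = 0.242 with an estimated correlation. Its median level in control 4 lay 0.42 above the control mean, without that liver 35 members were higher and 2 lower, without control 3 there were 32 and 4, and 32 of its 46 genes also stand in other lists. In the list of the ZFP36 family and the deadenylation machinery, 2 of 27 rose and 10 fell (2 and 10 adjusted over the list alone), with a camera adjusted p = 0.00916 and adjusted p = 0.11 with an estimated correlation. The deleted Zfp36l1 and Zfp36l2 are among these falls, and without them, a count made after the values were seen, 2 of 25 rose and 8 fell (2 and 8 adjusted over the list alone), with a camera adjusted p = 0.047, and adjusted p = 0.226 with an estimated correlation. Btg2, an antiproliferative gene, rose from 216 ± 101 to 1722 ± 368, while Cnot1, the scaffold of the CCR4-NOT deadenylase complex, fell from 2377 ± 122 to 1637 ± 189.

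The same question was put to the sequence of the 3' UTRs. The heptamer TATTTAT, the core of the element the family binds, stood in the annotated 3' UTRs of 33.1% of the 4006 genes higher in dKO livers and 29.6% of the 8483 genes called neither way (odds ratio 1.17, 95% interval 1.08 to 1.27, Fisher's exact test, 2-sided, p = 0.000132). The odds ratio was 1.05 (0.961 to 1.15, p = 0.285) in a logistic model with 3' UTR length and expression, and 1.01 for genes higher by 2-fold or more (Fisher's exact test p = 0.818). Among the 3028 genes lower in dKO livers the share was 26.6% (odds ratio 0.861, 0.783 to 0.946, Fisher's exact test p = 0.00161), and the modelled odds ratio was 0.773 (0.694 to 0.862, p = 3.6e-06). Without dKO 3 the odds ratio of the lower genes was 0.920 (Fisher's exact test p = 0.0782), and the modelled odds ratio was 0.804 (logistic model p = 8.6e-05).

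Markers of monocytes, recruited macrophages and neutrophils were higher in dKO livers. Of 24 tested markers of monocytes and recruited macrophages, 23 rose, 0 fell and 1 did neither (24 and 0 adjusted over the list alone), with a median log2 change of 2.20. Cybb, a subunit of the phagocyte NADPH oxidase, rose from 404 ± 137 to 2507 ± 349 (log2 change 2.68, SE 0.19, limma adjusted p = 6.7e-07), Cd9 from 280 ± 62.8 to 1366 ± 74.5 and Plac8 from 90.6 ± 9.09 to 388 ± 59. Trem2, a receptor of lipid-associated macrophages, rose from 32.2 ± 39.6 to 210 ± 63.9 (log2 change 3.28, SE 0.54), and by 4.00 without control 4. All 16 neutrophil markers rose, as they did adjusted over the list alone (16), with a median of 2.67, or 2.63 with the 3 members at 0 reads in controls put at their bound. Csf3r, the receptor of granulocyte colony-stimulating factor, rose from 65 ± 23.2 to 269.7 ± 72.8. Lactotransferrin (Ltf), a granule protein, had 0 reads in all controls and 46.6 ± 25.2 in dKO livers, at least 14.6-fold higher. Ngp had 1 read in the controls and 266 in dKO livers, a ratio of 232 with a 95% counting interval of 41.3 to 9203. The monocyte list had a camera adjusted p = 3.7e-13, and adjusted p = 0.236 with an estimated correlation. For neutrophils the camera adjusted p = 7.2e-07, and adjusted p = 0.0491 with an estimated correlation. Control 4 lay 0.85 above the control mean for the median monocyte marker and 0.62 for the median neutrophil marker, and without it 24 and 15 members were higher.

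Markers of resident macrophages and lymphocytes were examined next. Of 16 Kupffer cell markers 7 rose, 1 fell and 8 did neither (8 and 1 adjusted over the list alone), and the complement gene C1qb rose from 938 ± 23.8 to 2511 ± 307, with a camera adjusted p = 0.0163, and adjusted p = 0.558 with an estimated correlation. Clec4f, restricted to Kupffer cells in mice, stood at 2208 ± 286 in controls and 2144 ± 571 in dKO livers (limma adjusted p = 0.769). Timd4, a marker of long-resident Kupffer cells, stood at 138 ± 23.1 and 90.6 ± 55.1. Its limma adjusted p of 0.104 ranged from 0.0342 without dKO 1 to 0.288 without dKO 2, and was 0.0385 without dKO 4 and 0.0464 with quantile normalization. Of 25 T and NK cell markers 7 rose, 0 fell and 18 did neither (7 and 0 adjusted over the list alone), among them Thy1, from 19.2 ± 12.6 to 104 ± 21.7. With quantile normalization 3 of them rose (median 0.39 against 0.74), and 4 did without control 3. That list's camera adjusted p = 0.0495, and adjusted p = 0.345 with an estimated correlation, was over 0.05 in 14 of 21 other settings (0.0239 to 0.162 over all of them), including those that left out any 1 liver except control 2 or dKO 3 (0.0542 to 0.0849). Among 16 B and plasma cell markers 4 rose, 4 fell and 8 did neither (4 and 4 adjusted over the list alone), with 2 falls among the 10 that edgeR tested and 1 among the 9 left by a filter at a mean of 10. Cd74, the invariant chain of class II molecules that macrophages also express, rose from 1331 ± 288 to 4975 ± 665, and Ighd, the constant region of immunoglobulin D, fell from 23.2 ± 13.4 to 5.34 ± 0.948 (camera adjusted p of the list = 0.907, median 0.01, or -0.31 with quantile normalization, and mean -0.23).

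Genes of inflammatory signalling were examined beside these markers. Of 35 cytokines and chemokines 25 rose, 2 fell and 8 did neither (28 and 2 adjusted over the list alone), median 1.71, with a camera adjusted p = 1.8e-07, and adjusted p = 0.242 with an estimated correlation. Cxcl14 rose from 28.7 ± 19 to 2406 ± 673 (log2 change 6.61, SE 0.41, limma adjusted p = 1.7e-07), Cxcl16 from 133 ± 7.04 to 375 ± 29.4 and the neutrophil chemokine Cxcl1 from 209.7 ± 123 to 704 ± 284. The monocyte chemokine Ccl2 rose from 15.2 ± 18.4 to 285 ± 98.4 (log2 change 4.85, SE 0.64), and by 4.23 without control 3 and 5.58 without control 4. Control 4 lay 0.67 above the control mean for the median member, and without it 27 were higher and 1 lower. Of 30 interferon-stimulated genes 18 rose, 2 fell and 10 did neither (20 and 2 adjusted over the list alone), among them Usp18, from 183 ± 20.9 to 508 ± 22.2, and Zbp1, from 128 ± 10.5 to 347 ± 37.7, with a camera adjusted p = 5.0e-06, and adjusted p = 0.171 with an estimated correlation. Of 25 acute phase genes 13 rose, 5 fell and 7 did neither (13 and 6 adjusted over the list alone). Cebpd, a transcription factor of this response, rose from 209 ± 34.9 to 653 ± 69.7, and C-reactive protein (Crp) fell from 7822 ± 835 to 4206 ± 98.7. The acute phase list's camera adjusted p = 0.0667 ranged from 0.00191 to 0.152 over 21 other settings and was under 0.05 in 5 of them, among them quantile normalization and the settings without control 1 (0.032), without control 4 (0.0477) and without dKO 3 (0.0222).

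Extracellular matrix genes were higher in dKO livers. Of 37 tested members of the fibrosis list 35 rose, 1 fell and 1 did neither (35 and 1 adjusted over the list alone), with a median log2 change of 2.15. The basement membrane collagens Col4a1 and Col4a2 rose from 734 ± 107 to 4558 ± 686 and from 539 ± 68.3 to 3262 ± 379.9 (log2 change 2.60, SE 0.11, limma adjusted p = 1.2e-08 for the latter), and the membrane-bound protease Mmp14 from 725 ± 48 to 1876 ± 109. Col1a1, the main fibrillar collagen, rose from 679 ± 753 to 6057 ± 867 (log2 change 3.71, SE 0.49), and by 4.36 without control 4. The list had a camera adjusted p = 3.5e-16, and adjusted p = 0.236 with an estimated correlation. In control 4 the median member lay 0.73 above the control mean, and without that liver 35 were higher, with a median of 2.47. Stellate cell and myofibroblast markers were mixed: of 24, 10 rose, 4 fell and 10 did neither (10 and 4 adjusted over the list alone). Pdgfrb, a growth factor receptor of stellate cells, rose from 155 ± 46.3 to 693 ± 134, and Cygb from 132 ± 45.8 to 663 ± 87.7. Acta2, the smooth muscle actin of activated stellate cells, stood at 223 ± 200.4 and 367 ± 106, and its limma adjusted p of 0.145 ranged from 0.021 without control 4 (log2 change 2.02) to 0.51 with DESeq2, with a log2 change of 0.46 without control 3. The stellate list's camera adjusted p = 0.131 became 0.0334 without control 4, with a range of 0.0334 to 0.294 over 21 settings.

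Markers of bile duct and ductular cells also rose. Of 30 members 24 rose, 0 fell and 6 did neither (24 and 0 adjusted over the list alone), median 1.61, with a camera adjusted p = 1.0e-08, and adjusted p = 0.0956 with an estimated correlation. Spp1 (osteopontin) rose from 705 ± 365 to 9498 ± 1900.4 (log2 change 3.85, SE 0.25, limma adjusted p = 2.9e-07), Prom1 from 28.4 ± 7.13 to 362 ± 103 and the keratin Krt18, which hepatocytes also express, from 2439.7 ± 324 to 10522 ± 1350.5. The ductal transcription factor Sox9 rose from 108 ± 11.7 to 202 ± 57.1. Epcam rose from 25.4 ± 13.3 to 74.9 ± 29, with overlap between the groups. Krt19, a keratin of bile duct cells, rose from 38.9 ± 20.8 to 99 ± 50.1 with overlap (log2 change 1.38, SE 0.45, limma adjusted p = 0.0277). This call was lost without control 2 (0.0661), control 3 (0.067), dKO 1 (0.089) or dKO 4 (0.0853), with robust variances (0.0666) and with quantile normalization (0.0894), in a range from 0.00117. Sinusoidal endothelial markers went both ways: of 22, 6 rose, 6 fell and 10 did neither (6 and 6 adjusted over the list alone), with a camera adjusted p = 0.907. Cdh5, an adhesion molecule of endothelial junctions, rose from 603 ± 79.99 to 1026 ± 159, while Dpp4 fell from 2512 ± 78.7 to 1834 ± 89.5 and Ehd3 from 1403 ± 214 to 869.8 ± 21.2. Among 32 genes of growth factor, TGF-beta, Notch and YAP signalling 19 rose, 2 fell and 11 did neither (19 and 3 adjusted over the list alone), including the TGF-beta receptor Tgfbr2, from 568 ± 68.4 to 1711 ± 238, and the YAP target Ccn2, from 125 ± 28.9 to 548 ± 71.4, with a camera adjusted p = 0.000134, and adjusted p = 0.057 with an estimated correlation.

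Cell cycle and fetal liver genes were examined as groups that are low in the adult liver. Of 34 proliferation genes 29 rose, 1 fell and 4 did neither (32 and 1 adjusted over the list alone), median 1.47, with a camera adjusted p = 9.2e-10, and adjusted p = 0.242 with an estimated correlation. Mki67 rose from 85.8 ± 25.2 to 294 ± 34.9 (log2 change 1.81, SE 0.19, limma adjusted p = 1.1e-05) and Rrm2, a subunit of ribonucleotide reductase, from 84.2 ± 8.66 to 223 ± 31.7. For the median proliferation gene, control 4 lay 0.42 above the control mean, and 30 members were higher without it. Of 24 oncofetal and liver tumour-associated genes 18 rose, 0 fell and 6 did neither (19 and 1 adjusted over the list alone), median 2.28, or 2.22 with the 1 member at 0 reads in controls at its bound, with a camera adjusted p = 2.2e-09, and adjusted p = 0.0491 with an estimated correlation. Ly6d rose from 14 ± 2.58 to 1119 ± 349.7 (log2 change 6.23, SE 0.22, limma adjusted p = 3.5e-09), Golm1 from 69.9 ± 21 to 548 ± 53.7 and the imprinted long non-coding RNA H19 from 4.49 ± 1.51 to 242 ± 118. Afp, alpha-fetoprotein, rose from 44 ± 14.3 to 121 ± 18.9, and Igf2 stood at 14.2 ± 9.36 and 23.4 ± 11.6 (limma adjusted p = 0.234). Of 33 immediate early genes 24 rose, 0 fell and 9 did neither (24 and 1 adjusted over the list alone), among them Jun, from 309.8 ± 47.5 to 1288 ± 260, with a camera adjusted p = 1.3e-07, and adjusted p = 0.242 with an estimated correlation. Control 4 lay 0.47 above the control mean for the median immediate early gene and 0.05 for the median oncofetal gene.

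**Figure D3:**
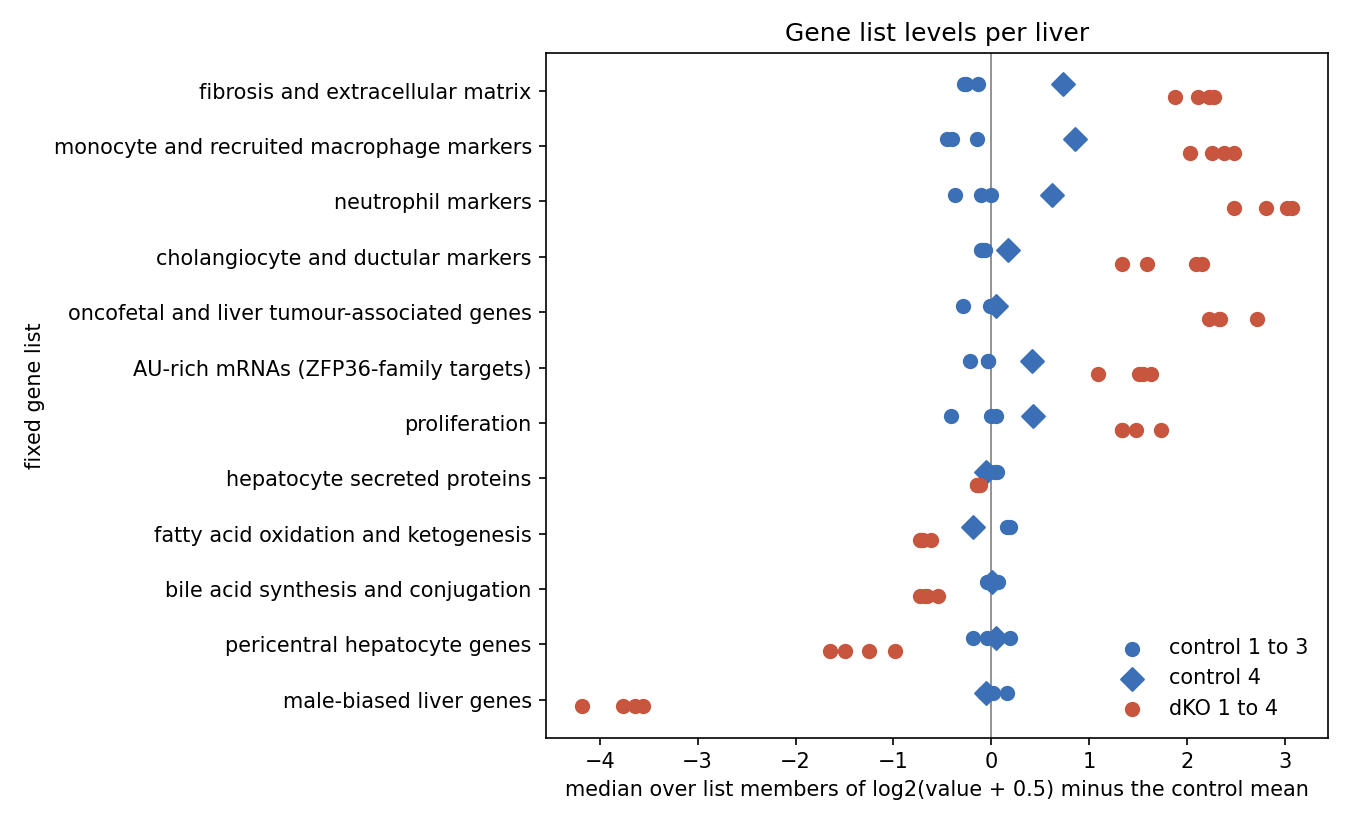
Level of 12 fixed gene lists in each liver (horizontal axis: median over the list's members of the log2 value minus the control mean); blue circles are controls 1 to 3, the blue diamond is control 4 and red circles are dKO livers. The dKO livers lie above all controls for the first 7 lists and below them for the last 5, with control 4 at 0.73 for fibrosis and extracellular matrix and 0.05 for oncofetal genes; with quantile normalization the median change of hepatocyte secreted proteins turned from -0.12 to 0.03.

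Genes with sex-biased expression in the liver showed the largest falls. Of 23 male-biased genes 0 rose, 19 fell and 4 did neither (0 and 19 adjusted over the list alone), with a median log2 change of -3.74 and a camera adjusted p = 8.7e-17, and adjusted p = 0.0491 with an estimated correlation. Hsd3b5, a steroid dehydrogenase of male liver, had 5498 reads in the controls and 2 in the dKO livers, 3150-fold lower with a 95% counting interval of 872 to 26020. Slco1a1, an organic anion transporter, fell from 5080.1 ± 453 to 50.03 ± 15.4 (log2 change -6.71, SE 0.19, limma adjusted p = 1.0e-09). Mup12, which encodes a major urinary protein, had 53432 reads in the controls and 1 in the dKO livers, and Mup17 fell from 16121 ± 10136 to 5.32 ± 4.08 (log2 change -11.38, and -12.14 without control 2). Reads of the near-identical Mup genes can be split between copies, so their single values are uncertain. Mup10 stood at 17710 in control 4 against 165 to 242 in the other controls, and its log2 change was -7.43, or -5.83 without control 4 and -8.08 without control 3. The sum over 19 Mup genes ranged from 170160 to 238090 in controls and from 4271 to 12206 in dKO livers. Among the 16 male-biased genes outside that family 12 fell, with a median of -2.27. Of 24 female-biased genes 13 rose, 3 fell and 8 did neither (14 and 4 adjusted over the list alone), median 1.79, or 1.66 with the 3 members at 0 reads in a group at their bound, with a camera adjusted p = 0.00301, and adjusted p = 0.345 with an estimated correlation. Cyp2a4, a steroid hydroxylase, rose from 84.9 ± 35.3 to 7515 ± 3829.9 (log2 change 6.44, SE 0.34, limma adjusted p = 5.5e-08), though it shares sequence with a close paralog. Cux2, a transcription factor of female liver, rose from 20.8 ± 7.44 to 839.7 ± 411, and the steroid hydroxylase Cyp17a1 from 216 ± 28.4 to 1236 ± 449.8.

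Genes of the zones of the liver lobule were examined by zone. Of 23 pericentral genes 2 rose, 21 fell and 0 did neither (2 and 21 adjusted over the list alone), median -1.43, with a camera adjusted p = 1.1e-11, and adjusted p = 0.171 with an estimated correlation. Cyp2e1, a cytochrome P450 of pericentral hepatocytes, fell from 141541 ± 19002 to 23289 ± 6603 (log2 change -2.64, SE 0.19, limma adjusted p = 5.4e-07), Cyp2c29 from 49211 ± 5152 to 6680 ± 1264 and Aldh1a1 from 31649.7 ± 3891 to 7649 ± 1346. Of 16 periportal genes 9 rose, 2 fell and 5 did neither (9 and 2 adjusted over the list alone), median 0.42, with a camera adjusted p = 0.00627, and adjusted p = 0.308 with an estimated correlation, and with quantile normalization 11 rose and 0 fell. Hsd17b13, a lipid droplet protein, rose from 4999.8 ± 410.4 to 10154 ± 629.7 and Aldh1b1 from 1343 ± 269.6 to 4349 ± 833. Among 30 genes of xenobiotic metabolism 5 rose, 18 fell and 7 did neither (6 and 19 adjusted over the list alone), with a camera adjusted p = 1.2e-05, and adjusted p = 0.308 with an estimated correlation, and with quantile normalization 8 rose and 18 fell. The sulfotransferase Sult1a1 rose from 3446 ± 491 to 13712 ± 1370.3, against the direction of Cyp2c29. Of 26 proteins secreted by hepatocytes 8 rose, 11 fell and 7 did neither (9 and 13 adjusted over the list alone), median -0.12, or 0.03 with quantile normalization. The antitrypsin genes Serpina1c and Serpina1e, members of a family of close copies, fell from 14704 ± 711 to 4034 ± 426 and from 49692 ± 16222 to 814 ± 154. Albumin (Alb) stood at 773160 ± 55865 in controls and 824048 ± 26104 in dKO livers (limma adjusted p = 0.785). The secreted protein list's camera adjusted p = 0.0427, and adjusted p = 0.469 with an estimated correlation, ranged from 3.6e-05 to 0.726 over 21 other settings, was lost in 5 of them, and was 0.0809 without dKO 3.

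Bile acid genes were examined as synthesis and transport. Of 16 genes of bile acid synthesis and conjugation 3 rose, 12 fell and 1 did neither (3 and 12 adjusted over the list alone), median -0.65, with a camera adjusted p = 4.2e-06, and adjusted p = 0.0491 with an estimated correlation. Hsd3b7, an early enzyme of all synthesis routes, fell from 13294 ± 487 to 3107 ± 35.1 (log2 change -2.10, SE 0.07, limma adjusted p = 1.9e-09), Akr1c6 from 19812 ± 1519 to 5129 ± 309 and Cyp7b1, of the alternative pathway, from 1913 ± 566 to 141 ± 29.7. Cyp8b1, which directs synthesis to cholic acid, fell from 5689 ± 1870.5 to 705 ± 449. Cyp7a1, the rate-limiting enzyme, rose from 1555 ± 1495 to 4444 ± 869.5 with overlap between the groups (limma adjusted p = 0.0047, 9.9e-06 to 0.055 over the alternatives, the highest with robust variances, which end the call). Among 15 transporters 6 rose, 6 fell and 3 did neither (6 and 6 adjusted over the list alone), with a camera adjusted p = 0.678, a median of -0.22, or 0.06 with quantile normalization, and a mean of 0.04. The bile salt export pump Abcb11 fell from 15831 ± 918 to 10812 ± 664, while the efflux pump Abcb1a rose from 120.1 ± 17.8 to 859.9 ± 108.

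Lipid and glucose genes gave a mixed picture outside fatty acid oxidation. Of 30 genes of fatty acid oxidation and ketogenesis 4 rose, 22 fell and 4 did neither (4 and 22 adjusted over the list alone), median -0.64, with a camera adjusted p = 5.8e-08, and adjusted p = 0.308 with an estimated correlation, and without dKO 3 there were 2 rises and 22 falls. Cyp4a10, an omega-hydroxylase induced by PPAR-alpha, fell from 8627 ± 3012 to 237 ± 149.6 (log2 change -5.38, SE 0.41, limma adjusted p = 9.3e-07), and Acadvl, the very long chain acyl-CoA dehydrogenase, from 4484 ± 433 to 2228 ± 187. Ucp2, a mitochondrial carrier on the same list, rose from 760 ± 96.9 to 2031 ± 327. Fgf21, a hepatic hormone, rose from 15.6 ± 9.47 to 50.2 ± 29.98 with overlap (limma adjusted p = 0.0139, 0.0501 without dKO 3 and 0.0719 with quantile normalization, in a range from 0.00247). Of 25 cholesterol synthesis genes 9 rose, 2 fell and 14 did neither (9 and 2 adjusted over the list alone), and 14 rose without control 3. The squalene synthase Fdft1 rose from 1595 ± 353 to 2796 ± 112. That list's camera adjusted p = 0.0427, and adjusted p = 0.759 with an estimated correlation, ranged from 0.00041 without control 3 to 0.277 without control 1 and was over 0.05 in 7 of 21 settings, including those without control 2 (0.0934), dKO 2 (0.0680) or dKO 3 (0.0585). Of 22 lipogenic genes 9 rose, 3 fell and 10 did neither (9 and 3 adjusted over the list alone), with a camera adjusted p = 0.418 that was 0.0299 with quantile normalization (0.0299 to 0.921 over 21 settings). The falls numbered 5 without dKO 3 and 1 without dKO 2, without dKO 4, with quantile normalization or with robust variances. Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, fell from 9058 ± 532 to 3109.8 ± 743 and the elongase Elovl6 rose from 831 ± 159 to 3220 ± 1704. Of 20 genes of lipid droplets and lipid uptake 8 rose, 7 fell and 5 did neither (8 and 7 adjusted over the list alone), with a camera adjusted p = 0.925, including Pparg, from 142 ± 15.8 to 424 ± 34.2, and the fatty acid binding protein Fabp1, which fell from 33687 ± 2252 to 11687 ± 2811. Of 21 genes of gluconeogenesis and glycogen 7 rose, 3 fell and 11 did neither (7 and 3 adjusted over the list alone), with 6 rises and 5 falls without control 4, and a camera adjusted p = 0.399 that was 0.0218 with quantile normalization (0.0218 to 0.779 over 21 settings). Ppp1r3c, a glycogen-targeting phosphatase subunit, fell from 1461 ± 328 to 236 ± 32.9 and the serine dehydratase Sds rose from 3693 ± 504 to 8068 ± 1406.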

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

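Of the tests here, those on control 4 were chosen after its values had been seen, and the counts over other splits of the livers were planned. Single livers stood apart from the other 3 of their group in 30 of 380 groups examined (188 genes, the read total and the mitochondrial share, each in both groups), by a gap to the nearest liver, as a share of the group's range, past the 95% critical value of Dixon's test. Chance flags about 1 in 20 groups, or 5%, against 7.89% here. Gldn, Aqp7, Ngp, Mup12, Mup1 and Mup19 had reads in only 1 liver of the flagged group, where the gap is always the whole range. The 5% does not hold for such groups, so the shares are not like for like. Control 4 accounted for 9 of the 30 flags, all high, and control 1 for 0.

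In control 4, Col1a1 stood at 1799 against 212 to 439.5 in the other controls (gap 0.857 of the range), Trem2 at 91.5 against 10.3 to 14.7 (0.945), Tnf at 21.7 against 1.03 to 3.08 (0.901), Spp1 at 1247 against 476.5 to 601 (0.839), Igdcc4 at 10.3 against 2.05 to 3.16 (0.866) and Nr1d1 at 3290 against 2767 to 2816 (0.906). Gldn and Aqp7 each had their 1 control read there (1, the whole range), and Aqp7 had 82 reads in dKO livers, a ratio of 71.6 with a 95% counting interval of 12.5 to 2860. Mup10 stood at 17710 against 165 to 242 (0.996) and its log2 change was -7.43, or -5.83 without control 4 and -8.08 without control 3. Col1a1 rose by 3.71 over all livers and 4.36 without control 4, Trem2 by 3.28 and 4.00, and Tnf by 2.94 and 3.80.

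Zfp36l2 was low in control 3, at 997 against 1722 to 1820 in the other controls (0.881), and it fell by 1.17 on the log2 scale without that liver. Jun was low there as well, at 239 against 328 to 336 (0.919), and Ngp had its only control read there (1, the whole range). In control 2, Noct stood at 562 against 173 to 238 (0.832) and Hbb-bt at 335.5 against 251 to 264 (0.839), with limma adjusted p of 0.00199 to 0.0621 over the alternatives for Hbb-bt, past the threshold except with robust variances. In dKO 4, Zfp36l1 stood at 267 against 209.5 to 214 (0.919), Myc at 276.5 against 201 to 208 (0.906), Ucp2 at 2521 against 1855 to 1894 (0.942) and Trem2 at 305 against 172 to 187 (0.887). Hba-a2 stood at 1505 there against 421.5 to 546 (0.885), with limma adjusted p of 0.00142 to 0.0604 over the alternatives, the highest with robust variances, and Mup19 had its only dKO reads there (1, the whole range), with a log2 change of -7.93, or -8.70 without that liver. In dKO 1, Col4a1 was low at 3536 against 4788 to 4956 (0.881), Col1a1 low at 4766 against 6348 to 6582 (0.871) and Vipr1 high at 409 against 305 to 310 (0.953). In dKO 2, Cd9 stood at 1477 against 1323 to 1333 (0.936), Cxcl14 at 3407 against 1964 to 2170 (0.857), Mup18 at 98 against 3.72 to 4.26 (0.994) and Mup12 had its only dKO read there (1, the whole range); the log2 change of Mup18 was -9.24, or -10.36 without that liver. In dKO 3, Fasn stood at 39360 against 11130 to 15570 (0.843), Lck at 40.9 against 21.3 to 23.3 (0.897), with a log2 change of 2.20, or 1.57 without control 3, and Mup1 had its only dKO read there (1, the whole range), with 2238 in controls, a ratio of 2565 with a 95% counting interval of 459.8 to 101300.

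The position of control 4 nearer to the dKO livers was weighed against a pair of technical explanations. If dKO RNA had been mixed into this library, all strongly raised genes would be shifted by about the share seen for the fibrosis list (median 23.7% of the way from controls 1 to 3 to the dKO mean), but for 54.0% of 139 such genes the upper bound of the 95% counting interval of the shift lay under 0.5 of that share, among them H19 at -0.595% and Ly6d at -0.17%. A mislabelled dKO liver is argued against by Zfp36l1, which stood at 6.15 times the highest dKO liver. The library may therefore hold a real difference of that liver, with more fibrosis and inflammation transcripts. No biological explanation was tested, since the labels name none within the control group.

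Other splits of the 8 livers into 4 and 4 were compared with the real one. Of 35 splits, only the real split (1) gave 4244 genes higher, 3410 lower, 2559 higher by 2-fold or more or 796 lower by 2-fold or more. The highest count of any other split was 1 in each case. Every other split mixes controls and dKO livers, which puts the difference between the groups into the spread within its sides. Low gene counts are therefore built into the other splits, and these splits cannot exclude chance. By the rule set before, the gene counts went against a chance split and the list counts went with it. For the fixed lists too, these splits do not decide the question. Counted in whichever direction gave more, 7 of 35 splits, the real one included, called as many lists as the 17 called higher, and 19 as many as the 9 called lower, with up to 18 in another split. The 6 others that reached 17 are among the 16 that keep 3 livers of each group together and so carry much of the real difference (11 to 18 lists), while the 18 that take 2 livers from each group called 1 to 11. The count of 19 sets the larger direction of the other splits against the smaller of the real one, which makes it too high, and in the smaller direction 1 other split reached 9. This division of the splits was made after their counts were seen.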

How the results depend on the processing

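Of the settings here, edgeR, DESeq2 and the filter at a mean of 10 were added after the values were seen. Zfp36l1 and Zfp36l2 were lower and past the threshold in all 21 alternatives, with log2 changes of -2.68 to -2.50 and -1.17 to -0.88. Genes higher numbered 3638 to 4734 and genes lower 2715 to 4312. Quantile normalization shifted the median of all genes from 0.03 to -0.08, gave 1901 genes higher and 1339 lower by 2-fold or more against 2559 and 796 and 45.8% of calls higher against 55.4%, and equal totals gave a median of 0.10 and 63.5%. The shift follows from forcing equal distributions, and the cause of the changed 2-fold counts was not tested. Of the 7654 calls, 84.7% to 100% were shared with each alternative. Of 188 genes 14 changed a call in some alternative, as did 8 of 39 lists in the 21 alternatives other than the estimated correlation, and none reversed. The counts of rising or falling list members that moved by over 1.5 times and by 2 or more genes stand with their lists.

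With an estimated correlation camera called 2 lists higher and 2 lower, against 17 and 9, so that 22 calls were lost. The estimate allows for members that vary together. It was -0.0063 for the deadenylation list and 0.0112 for the growth factor list, below or near the preset 0.01, and these calls were lost too. Members that vary together therefore do not account for every loss, and the cause was not tested. The odds ratio of TATTTAT among genes higher was 1.08 with edgeR (Fisher's exact test p = 0.0881), 1.08 with the filter at a mean of 10 (p = 0.083) and 1.01 for 2-fold changes (p = 0.818), each no longer past the threshold; the cause was not tested. Among genes lower it ranged from 0.772 to 0.920 when livers were left out in turn, and the call was lost without dKO 3. With length and expression in the model, the odds ratio of the lower genes ranged from 0.721 to 0.804, past the threshold each time.

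The mouse numbers were not taken as pairs, since deviations of same-numbered mice correlated at 0.032, -0.069, 0.037 and 0.077. In 5 of 8 livers the best correlation was with their own number, against 2 expected by chance, so a weak link between numbers stays open. With the number as a replicate block 7133 genes were called, against 7654, none of the 188 genes changed its call and 1 list gained one. Depth limits genes under 3 counts per library, including 131 called genes with 0 reads in all controls and 30 with 0 in all dKO livers.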

Other observations

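Of the tests below, those on 3' UTR length, A/T content, the hepatocyte share and the Mup sum were chosen after the results were seen, while those on sex and on repeated motifs were set before. Hormone and clock genes were also among the fixed lists. Of 18 genes of the growth hormone and IGF axis 3 rose, 9 fell and 6 did neither (3 and 10 adjusted over the list alone), median -0.34. Ghr, the growth hormone receptor, fell from 10327 ± 595 to 4509 ± 452 (log2 change -1.20, SE 0.09, limma adjusted p = 5.6e-07) and Lifr from 5492 ± 762 to 2275 ± 242. The list's camera adjusted p = 0.0214, and adjusted p = 0.242 with an estimated correlation, ranged from 0.00498 to 0.26 over 21 other settings and was lost in 2, quantile normalization and the filter at a mean of 10. Of 21 clock genes 9 rose, 6 fell and 6 did neither (10 and 7 adjusted over the list alone), with a camera adjusted p = 0.399. Nr1d1, a repressor of the clock, fell from 2911 ± 254 to 609 ± 83.8, and Per2 rose from 266 ± 47.8 to 998 ± 74.6.

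Stress genes went both ways. Of 30 genes of the integrated stress and unfolded protein response 8 rose, 5 fell and 17 did neither (8 and 5 adjusted over the list alone), or 5 and 5 without dKO 2 and likewise without dKO 4, with a camera adjusted p = 0.513, among them the asparagine synthetase Asns, which rose from 58.9 ± 28.7 to 757 ± 174, and the transcription factor Atf3, from 16.9 ± 12.9 to 307 ± 98.3. Of 24 NRF2 targets 14 rose, 3 fell and 7 did neither (14 and 4 adjusted over the list alone), with a camera adjusted p = 0.00693, and adjusted p = 0.456 with an estimated correlation. Srxn1 rose from 841 ± 62.2 to 1777 ± 231, while the abundant Gsta3 and Gclc fell from 28243 ± 2943 to 10993 ± 502 and from 7584 ± 948 to 3486 ± 218. Of 22 p53 targets 7 rose, 4 fell and 11 did neither (8 and 4 adjusted over the list alone), with a camera adjusted p = 0.678, and Perp fell from 2117 ± 176 to 1279 ± 87.4. Among markers of blood 6 of 12 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.307), and 1 rose with robust variances. Alas2, an enzyme of erythroid heme synthesis, fell from 1275 ± 173 to 444 ± 184, and Hbb-bs rose from 1818 ± 369 to 4128 ± 2203 (limma adjusted p = 0.00704, 0.00242 to 0.0616 over the alternatives). Of 15 mitochondrially encoded genes 0 rose, 8 fell and 7 did neither (0 and 8 adjusted over the list alone), or 5 falls without dKO 2 and 5 with the mouse number as a replicate block, with a camera adjusted p = 0.00292, and adjusted p = 0.292 with an estimated correlation, among them mt-Nd4, from 65414 ± 5868 to 45536 ± 5408. Of 5 tested adipose markers 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.907, median -0.05, or 0.03 with equal totals, and mean 0.59), and Car3, which liver also expresses, fell from 30592 ± 4913 to 3588 ± 375. Of 3 tested pancreatic markers 1 fell, as adjusted over the list alone (1): Cela1, from 329 ± 79.3 to 114 ± 27.5.

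Male-biased genes fell (median log2 change -3.74), and female mice labelled male would lack Y-linked transcripts, but the summed Ddx3y, Eif2s3y, Kdm5d and Uty in the lowest dKO liver reached 77.2% of the control mean, with Xist at 0% to 0.0952% of that sum. A lower share of hepatocytes would lower hepatocyte proteins alike, but the lower quartile of the secreted protein list lay at -0.73, and reads shifted between Mup copies would leave their sum, which in the highest dKO liver was 7.17% of the lowest control. The Mup sum replaced an undecided test, in which the upper quartile of the 16 members outside that family lay at -0.69, above the bound of -1 set for it. An effect of the deletion itself stays open, by a route not tested here, and genes of growth hormone signalling went both ways. Among genes picked after their values were seen, Stat5b fell from 1942 ± 228 to 1201 ± 153, Bcl6 fell from 1164 ± 646 to 409.9 ± 74.3 with overlap (limma adjusted p = 0.0143, 2.0e-05 to 0.0946 over the alternatives) and Socs2, a feedback target that growth hormone induces, rose from 149 ± 55.9 to 510.3 ± 181, opposite to what lower signalling would give.

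The higher share of TATTTAT among genes that rose (odds ratio 1.17) was weighed against features of the 3' UTRs. Longer 3' UTRs of these genes (median 1219 against 1106 bases) may account for it, since the odds ratio was 1.05 (0.961 to 1.15) with length and expression in the model. The odds ratio was 1.16 (1.06 to 1.27) once A/T content was added, so the answer depends on the covariates and length stays open. This A/T content was that of the longest 3' UTR, while motif and length were taken from the union of 3' UTRs. The test as first set, without A/T content, went with length as the cause, though it could not part length from expression. Genes lower in dKO livers also had longer 3' UTRs (median 1240 bases), but a smaller share of them held TATTTAT (26.6% against 29.6%). Length alone therefore does not account for the shares in both directions. A/T content of the longest 3' UTR alone is argued against by that value of 1.16. The test set before asked for rank 1 or 2 among 21 heptamers of 2 A and 5 T and an interval without 1. It stayed undecided, since TATTTAT ranked 1 and its interval included 1. TATTTAT, TTATTTA and ATTTATT, which hold ATTTA, ranked 1 to 3 in both directions, though among genes higher their intervals included 1. The other heptamers had modelled odds ratios of 0.755 to 0.957 among genes higher. Among genes lower these 3 stood at 0.773, 0.805 and 0.807, and the others at 0.899 to 1.14. Such differences at equal A/T content also argue against A/T content alone, though this grouping was not set before. The hypothesis that mRNAs with 3 or more copies rise with the loss of these proteins gave an odds ratio of 1.02 (0.841 to 1.25) against genes with none. This met the bound set before for no such rise (an estimate under 1.2 with 1 in the interval). The interval reaches past 1.2, so a modest effect stays open. Among genes lower in dKO livers the same modelled comparison gave an odds ratio of 0.665 (0.512 to 0.863). Both comparisons of 3 or more copies used the longest 3' UTR of each gene. For any copy among genes lower, the odds ratio was 0.746 in the longest 3' UTR and 0.773 (0.694 to 0.862) in the union. Both values lie within the interval for 3 or more copies, so they do not show whether more copies matter.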
